A study of Mus musculus with 11 samples.

How the data were processed

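The samples were 11 tumors from a mouse model of small cell lung cancer, a neuroendocrine carcinoma. Per the labels, the genotype combined Rb and p53 alleles with a doxycycline-responsive MYCN transgene (TRE-MYCN) and a Cre-dependent doxycycline transactivator (LSL-RTTA). The MYCN ON group held 7 tumors on doxycycline. The MYCN OFF group held 4 tumors whose doxycycline was withdrawn 7 days earlier. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the tumors came from separate mice, so the p-values measure the spread between these tumors.

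Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected with oligo-dT beads and libraries were made with the NEBNext Ultra RNA kit. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, TopHat2 2.0.8b and HTSeq 0.6.1 with the mouse build mm9. The gene annotation, alignment options and strand setting were not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The authors deposited whole-number read counts per gene symbol for each tumor, with no normalization. Each file listed 23284 genes and 5 summary rows that name no gene. The summary rows stayed out of library sizes and tests. Reads with no annotated gene made up 14.8% to 21.5% of the records of a tumor. Reads aligned to several places made up 9.15% to 20.9% and were not counted for any gene. Families with near-identical copies or processed pseudogenes, such as ribosomal proteins and MHC class I, can lose reads in this way, and their values are uncertain to that extent. The reference annotation in use here was of another mouse build, so it served only for transcript length and GC content and no coordinates are given.

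Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 15237 genes. Libraries were scaled by TMM factors, and values per tumor are depth-scaled counts (CPM) with those factors. The quasi-likelihood test with robust dispersion compared the groups with no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are MYCN ON over MYCN OFF, and the standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM values are mean ± SD over 7 MYCN ON and 4 MYCN OFF tumors.

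Gene lists, 35 in number, were also fixed in advance, and 33 had at least 5 tested members. Hepatocyte markers (4 tested) and erythroid markers (1 tested) were therefore left out of the list tests. Each list was described by its called members, over all genes tested and adjusted over the list alone. Each list also had a score per tumor, the mean of log2 CPM (prior count 2) over its members, compared by a two-sided exact permutation test. The 330 ways to choose 4 of 11 tumors give a smallest possible p of 0.00303, and the score p-values were adjusted over 33 lists. Camera from limma 3.58.1 was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and fry was run for direction.

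Named genes followed a rule fixed in advance. It took Mycn, Myc, Mycl1, Usp7, Neurod1, Rb1 and Trp53 in every case. It added the 12 genes in each direction with the smallest p among called genes with an absolute log2 fold change of at least 1 and a mean of at least 1 CPM in the higher group, leaving out unnamed transcripts and small RNA genes. Lists that passed camera or had at least 3 called members gave up to 4 members with the smallest p, and other lists up to 2. Sftpc, Scgb1a1, H2-K1, B2m, Calca and Chga were chosen after their values were seen, as were the genes of the additional lists among the closing observations. Some genes that the rule takes are not reported here.

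The test was checked on simulated counts for the 15237 genes, with 200 genes changed. It recovered 9% of the 2-fold and 67% of the 4-fold changes, and 6.17% of its calls were false. These shares hold for 200 changed genes, far fewer than the comparison called, and the adjusted threshold is stricter when fewer genes change. Both changed lists were called by camera and by the permutation test, and 0 of the unchanged lists were. The simulated genes varied independently of each other, while the estimated inter-gene correlation was 0.859 for mitosis and 0.769 for ribosomal proteins. The simulation therefore does not show how often camera calls unchanged lists in these tumors. No pair of tumors of a group agreed within sampling noise: the smallest chi-square per gene was 51.2.

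Alternatives fixed before the data were examined were RLE and upper quartile factors, library totals alone, DESeq2 1.42.0, limma voom with and without sample quality weights, no and stricter low-count filters, the replicate number as a block, 1 surrogate variable from sva 3.50.0, an adjusted p below 0.01, a test for changes above 1.5-fold, each tumor left out in turn, and other priors and a median for the list scores. Lung and immune marker scores as covariates, and fits within tumors below and at or above 100 CPM of Sftpc, were added after seeing the data. The lung score is the mean of the alveolar and airway list scores, and the immune score that of the macrophage, T and NK, and B and plasma cell lists.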

Results

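Poly(A) RNA from 11 mouse small cell lung tumors was sequenced to compare tumors with the doxycycline-controlled MYCN transgene on and off. There were 7 tumors with doxycycline (MYCN ON) and 4 with doxycycline withdrawn for 7 days (MYCN OFF). Doxycycline and MYCN changed together, and no doxycycline-treated tumor without the transgene was included. Effects of MYCN and of the drug itself therefore cannot be told apart in any result below. Reads counted over genes ranged from 10324089 to 13123838 per tumor in MYCN ON and from 8951733 to 12190957 in MYCN OFF, and the MYCN ON libraries were deeper (n = 7 and 4, two-sided exact permutation p = 0.0424). The precision of the comparison was set mainly by the spread between tumors, with a biological coefficient of variation of 53.7%.

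Mycn counts were higher in every MYCN ON tumor than in every MYCN OFF tumor. The level was 102 ± 48.1 CPM in MYCN ON, with a range of 36.5 to 171, and 12.2 ± 4.51 CPM in MYCN OFF, with a range of 5.63 to 15.7. The log2 fold change was 3.06 (SE 0.47, edgeR adjusted p = 0.00139). The MYCN OFF tumors still held 60 to 192 Mycn reads each. The labels do not state the species of the transgene, and if it is not the mouse sequence only reads that also align to mouse Mycn were counted.

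Myc, the MYCN paralog, moved the other way, from 9.59 ± 1.73 CPM in MYCN OFF to 3.36 ± 1.24 CPM in MYCN ON (log2 fold change -1.51, SE 0.34, edgeR adjusted p = 0.00842). Max, the dimerization partner of the MYC family, was higher in MYCN ON with a log2 fold change of 0.71 (SE 0.16, adjusted p = 0.00766). Usp7, a deubiquitinase named in the title of the series, was higher at 313 ± 59.6 against 174 ± 25.3 CPM (log2 fold change 0.85, SE 0.17, adjusted p = 0.00531). Mycl1, with a log2 fold change of 0.45, was not called (adjusted p = 0.409). Of the 8 tested members of the MYC-family and subtype list, 3 were higher, 1 was lower and 4 were not called. The counts were the same adjusted over the list alone, and the list score did not pass the test (adjusted exact permutation p = 0.613; adjusted p = 0.449 by camera with an estimated correlation). With library totals as the only scaling, Usp7 (adjusted p = 0.0502) and Max (adjusted p = 0.0606) missed the threshold. With the lung marker score as a covariate, chosen after seeing the data, Myc missed it too (log2 fold change -1.13, adjusted p = 0.097).

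**Figure D1:**
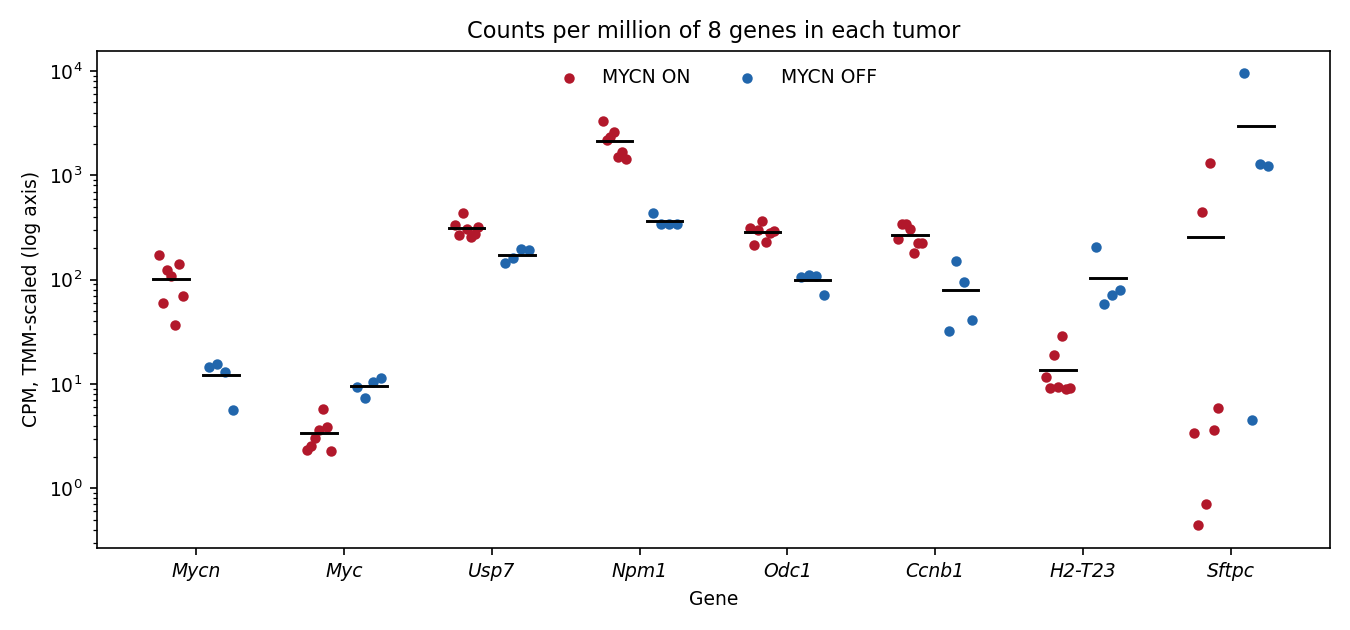
CPM of 8 genes on a log axis, 1 point per tumor, for 7 MYCN ON (red) and 4 MYCN OFF (blue) tumors, with a black bar at each group mean. Mycn ranges from 36.5 to 171 CPM in MYCN ON and from 5.63 to 15.7 CPM in MYCN OFF, and Sftpc, a lung alveolar transcript, ranges from 0.443 to 9505 CPM over the tumors.

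Expression differed broadly between the groups. Of 15237 genes tested, 2437 were higher and 2038 lower in MYCN ON at an edgeR adjusted p below 0.05, which is 29.4% of the genes. At least a 2-fold change was seen in 1204 of the higher and 1701 of the lower genes. The ranges of both groups did not overlap for 2564 genes, 16.8% of those tested against 0.606% by chance. The split between higher and lower calls depended on the scaling, since the TMM factors themselves separated the groups (0.835 to 1.01 in MYCN ON, 1.09 to 1.22 in MYCN OFF). The higher genes made up 54.5% of the calls with TMM, 48.0% with RLE factors, 37.0% with upper quartile factors and 28.2% with library totals, which gave 1317 genes higher in MYCN ON and 3347 genes lower in MYCN ON. Upper quartile factors and library totals moved the median of all genes by -0.21 and -0.31 on the log2 scale. Leaving out MYCN OFF tumor 1 gave 2862 calls, and leaving out MYCN OFF tumor 4 gave 2922.

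Lung tissue markers varied over orders of magnitude between the tumors and were unevenly spread over the groups. Sftpc, surfactant protein C of alveolar type II cells, was at 1227 to 9505 CPM in MYCN OFF tumors 1, 3 and 4 and in MYCN ON tumor 5 at 1313 CPM, at 450 CPM in MYCN ON tumor 3, and at most 5.86 CPM in the remaining tumors. Scgb1a1, the club cell secretory protein, reached 13912 CPM in MYCN OFF tumor 1. These differences between the groups were not called (edgeR adjusted p = 0.191 and 0.0885), and that of Scgb1a1 passed only in the fit without MYCN ON tumor 5 among those with 1 tumor left out (log2 fold change -7.38, adjusted p = 0.019). Limma voom with sample quality weights called both Sftpc (log2 fold change -5.94, adjusted p = 0.0341) and Scgb1a1 (-5.18, adjusted p = 0.0461), and DESeq2 called Scgb1a1 (adjusted p = 0.029). In the fit with quality weights MYCN OFF tumor 3 had a weight of 4.11, against 0.454 to 0.827 for the other MYCN OFF tumors, so it rests largely on that tumor. Sftpc and Scgb1a1 were chosen after their values were seen. With the lung score as a covariate, an alternative chosen after seeing the data, there were 927 genes higher in MYCN ON and 384 genes lower in MYCN ON, and 1241 of these 1311 were among the 4475 calls without it. Of 111 named genes, 36 lost their call with this covariate, 3 of them members of the lists behind the score. An immune marker score in its place ended 44 calls, 6 of them of its own members. Adjustment for their own mean lowers the difference of such members by construction. In the lung-poor tumors alone (5 MYCN ON, 1 MYCN OFF), edgeR called 0 genes, with 2288 at an unadjusted p below 0.05. DESeq2 called 830 and limma voom 3 there. In the lung-containing tumors alone (2 MYCN ON, 3 MYCN OFF), edgeR called 0, with 3898 at an unadjusted p below 0.05, DESeq2 2503 and limma voom 0. The sign of the difference was kept in the lung-poor tumors by 2436 of 2437 genes called higher and 1817 of 1947 called lower in all tumors, and in the lung-containing tumors by 2430 of 2430 and 2038 of 2038. These genes were called on the same tumors, so the shares are not independent evidence.

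Apex1, Mif and Dkc1 were among the genes with the smallest p higher in MYCN ON. Apex1, the abasic-site endonuclease of base excision repair, was at 50.2 ± 10.6 against 7.93 ± 0.896 CPM (log2 fold change 2.66, SE 0.21, edgeR adjusted p = 2.25e-04). Mif, the macrophage migration inhibitory factor, was at 553 ± 111 against 106 ± 8.94 CPM, with a log2 fold change of 2.39 and the same adjusted p, although its pseudogene copies make the level uncertain. Dkc1, the pseudouridine synthase of box H/ACA particles, rose 4.51-fold, from 55.0 ± 0.881 to 249 ± 54.7 CPM. Taf1d, a subunit of the RNA polymerase I factor SL1, rose 3.46-fold, Twistnb, a polymerase I subunit, 3.37-fold, and Rrp15, a ribosome assembly factor, 3.65-fold. Bzw2 (4.83-fold), Idi1 (4.03-fold), Nlrp1a (3.48-fold), Mbtd1 (3.23-fold), Erh (2.97-fold) and Naa15 (2.75-fold) completed the set, with adjusted p-values of at most 3.18e-04. Nlrp1a belongs to a gene cluster of close copies and is uncertain for that reason.

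Among the genes lower in MYCN ON, Vil1, the actin bundler villin, had the smallest p and was 7.44-fold higher in MYCN OFF (log2 fold change -2.89, SE 0.29, edgeR adjusted p = 3.28e-04). Dhx58, the RNA helicase LGP2 of the RIG-I family, was 8.09-fold higher in MYCN OFF, Scml4 6.28-fold and Spsb2 5.40-fold. Nr1d1, the clock repressor REV-ERB alpha, was 3.68-fold higher in MYCN OFF, and Wfs1, an endoplasmic reticulum membrane protein, 3.49-fold. Tnfrsf1a, the TNF receptor 1, was at 24.6 ± 2.97 CPM in MYCN ON against 64.4 ± 9.47 in MYCN OFF. Nkd1 (2.87-fold), Znfx1 (2.84-fold), Aldh3a2 (2.82-fold), Mov10 (2.59-fold) and Mgat1 (2.51-fold) had adjusted p-values of at most 7.16e-04. All 12 kept their direction and call with the lung score as a covariate and with each tumor left out in turn.

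**Figure D2:**
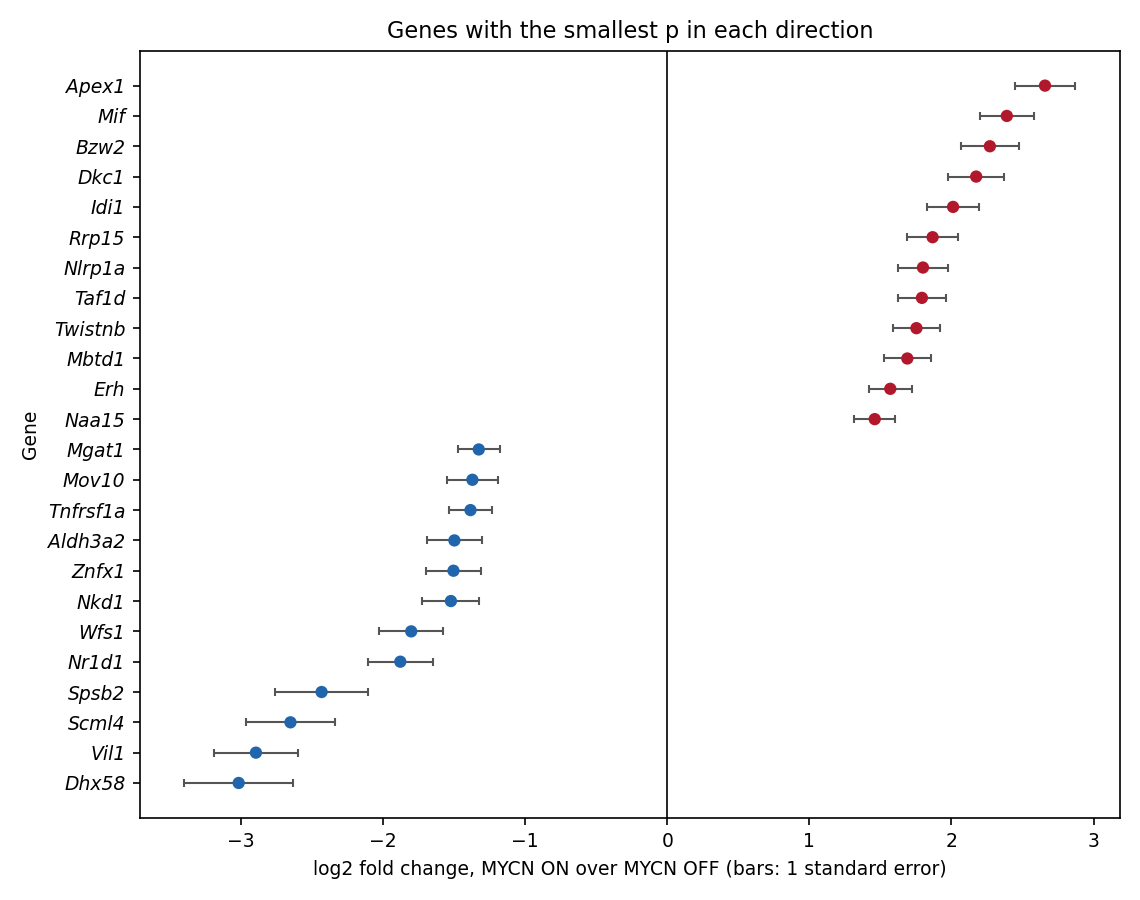
Log2 fold change of the 12 genes with the smallest p in each direction, MYCN ON over MYCN OFF, with bars of 1 standard error from the edgeR fit of 7 and 4 tumors. Values run from 2.66 for Apex1 to -3.02 for Dhx58.

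Genes for making ribosomes and for translation were higher together in MYCN ON. Of 30 tested nucleolar ribosome biogenesis genes, 28 were higher and 0 lower, with 29 higher adjusted over the list alone. Npm1, the nucleolar chaperone nucleophosmin, was at 2147 ± 679 against 366 ± 49.2 CPM (log2 fold change 2.55, SE 0.27, edgeR adjusted p = 3.43e-04). Polr1b, the second largest subunit of RNA polymerase I, rose 3.94-fold and Nop58, a box C/D particle core protein, 3.98-fold. All 36 ribosomal protein genes tested were higher, and all 36 also adjusted over the list alone. Rplp0 rose 3.57-fold and Rpl4 2.83-fold, and reads shared with their many processed pseudogenes were not counted. Of 20 translation initiation and elongation factors, 16 were higher (18 adjusted over the list alone), among them Eif4a1 (3.62-fold) and the cap-binding protein Eif4e (2.53-fold). The list scores (mean log2 CPM) were 7.06 ± 0.34 against 5.57 ± 0.13 for ribosome biogenesis, 9.88 ± 0.32 against 8.48 ± 0.41 for ribosomal proteins and 8.24 ± 0.22 against 7.11 ± 0.089 for translation factors, each with every MYCN ON tumor above every MYCN OFF tumor (adjusted exact permutation p = 0.00909). By camera with an estimated correlation the adjusted p-values were 0.176, 0.215 and 0.176. In the fit with the lung score as a covariate, 15, 19 and 10 members were called, all higher. In the lung-poor MYCN OFF tumor 2 the scores were 5.76, 8.05 and 7.15, below the lowest lung-poor MYCN ON values of 6.85, 9.63 and 8.04. It was the only lung-poor MYCN OFF tumor, and its muscle list score of 4.38 exceeded the highest lung-poor MYCN ON value of 1.24. Low lung markers therefore do not make this tumor free of other tissue, here or in the comparisons with it below.

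Metabolic lists moved in the same direction. Nucleotide synthesis had 18 of 24 members higher (20 adjusted over the list alone), including Nme1, a nucleoside diphosphate kinase, at 3.05-fold, and Ppat, the first committed enzyme of purine synthesis, at 3.08-fold. Of 15 polyamine, serine and one-carbon genes, 10 were higher and 0 lower, and 11 were higher and 1 lower adjusted over the list alone. Odc1, ornithine decarboxylase, was at 285 ± 50.7 against 99.3 ± 18.5 CPM (log2 fold change 1.52, SE 0.19, edgeR adjusted p = 6.08e-04), and Shmt1 rose 4.64-fold. In glycolysis 9 of 18 genes were higher (10 adjusted over the list alone), with Ldha, lactate dehydrogenase A, at 4.54-fold and Pkm2 at 3.13-fold. Oxidative phosphorylation had 15 of 25 members higher (18 adjusted over the list alone), such as Cox5a at 2.16-fold and Uqcrfs1 at 1.99-fold. Mitochondrial ribosome genes had 13 of 20 higher (13 adjusted over the list alone), such as Mrps5 at 2.23-fold and Mrpl12 at 2.04-fold. The adjusted exact permutation p of the score was 0.0333 for glycolysis and 0.00909 for the other 4 lists. By camera with an estimated correlation, the adjusted p was 0.215 for nucleotide synthesis, 0.176 for the polyamine list, 0.344 for glycolysis, 0.176 for oxidative phosphorylation and 0.243 for the mitochondrial ribosome. With the lung score as a covariate, 7, 7, 4, 7 and 5 members of these lists were called. A member was lower in the polyamine list without MYCN ON tumor 3, MYCN ON tumor 5 or MYCN OFF tumor 2, and in glycolysis without MYCN ON tumor 7. With library totals as the scaling, 8 oxidative phosphorylation and 7 mitochondrial ribosome genes were called higher. The lung-poor MYCN OFF tumor 2 had a glycolysis score of 6.50, within the 6.39 to 7.69 of the lung-poor MYCN ON tumors, and lay below them in the other 4 scores.

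Cell-cycle genes were on average higher in MYCN ON, but MYCN OFF tumor 2 lay with the MYCN ON tumors. Of 30 mitosis genes, 15 were higher and 0 lower (20 higher adjusted over the list alone), and Ccnb1, cyclin B1, was at 267 ± 64.7 against 80.0 ± 55.6 CPM (log2 fold change 1.74, SE 0.40, edgeR adjusted p = 0.0096). Mad2l1, a spindle checkpoint protein, was at 112 ± 28.4 against 39.3 ± 23.7 CPM. DNA replication had 10 of 30 members higher (12 adjusted over the list alone), among them Gins1 at 2.41-fold and the helicase subunit Mcm4 at 1.98-fold. DNA damage response and repair had 9 of 30 higher (12 adjusted over the list alone), with Chek2 at 3.36-fold and Parp1 at 2.42-fold. The adjusted exact permutation p of the scores was 0.025, 0.0154 and 0.0294 for mitosis, replication and repair, and by camera with an estimated correlation the adjusted p was 0.397, 0.426 and 0.397. The mitosis score of the lung-poor MYCN OFF tumor 2 was 7.24, within the 7.06 to 7.90 of the lung-poor MYCN ON tumors. The lung-rich MYCN OFF tumors 1, 3 and 4 lay at 4.77, 6.50 and 5.03. The lung-containing MYCN ON tumors 3 and 5 lay above each of these, at 7.57 and 7.13. Limma voom called 23 mitosis genes. Without MYCN OFF tumor 2, 30 mitosis, 20 replication and 20 repair genes were called. Leaving out tumor 1 gave 6 mitosis and 5 replication genes, leaving out tumor 4 gave 5 and 5, and leaving out MYCN ON tumor 3 gave 6 replication genes. With library totals as the scaling 7 mitosis and 5 replication genes were called. With the lung score as a covariate edgeR called 0 mitosis genes (15 at an unadjusted p below 0.05, DESeq2 2, limma voom 0), 0 replication genes (7, DESeq2 3, limma voom 0) and 3 repair genes.

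The scores of p53 target genes and of immediate early genes were lower in MYCN ON. Of 20 p53 target genes, 1 was higher and 4 were lower in MYCN ON, and as many adjusted over the list alone, while DESeq2 called 10. Cdkn1a, the cell-cycle inhibitor p21, was at 34.7 ± 17.5 against 121 ± 31.5 CPM (log2 fold change -1.80, SE 0.31, edgeR adjusted p = 0.00231), and Phlda3 and Btg2 were 3.83-fold and 2.28-fold higher in MYCN OFF. Aen, an apoptosis-enhancing nuclease, was the member that was higher in MYCN ON, at 2.23-fold. The p53 target score was lower in every MYCN ON tumor (difference -0.63, adjusted exact permutation p = 0.00909; adjusted p = 0.176 by camera with an estimated correlation). Trp53 itself was not called (log2 fold change -0.20, adjusted p = 0.6). The genotype included p53 alleles and bulk counts do not separate the cells, so p53 activity of tumor cells cannot be read from these genes. Immediate early and heat shock genes, which respond to handling, had 8 of 19 lower (12 adjusted over the list alone), among them Junb and Egr1, with 2.91-fold and 3.32-fold higher levels in MYCN OFF. Their score was lower in every MYCN ON tumor than in every MYCN OFF tumor (adjusted exact permutation p = 0.00909; adjusted p = 0.215 by camera with an estimated correlation). With library totals as the scaling 10 p53 targets and 13 immediate early genes were lower, and with the lung score as a covariate 2 and 1 were, while Phlda3, Btg2, Aen, Junb and Egr1 lost their call. Leaving out MYCN OFF tumor 4 gave 3 immediate early genes, and leaving out tumor 1 gave 5. In the lung-poor MYCN OFF tumor 2 the p53 target score was 4.96, above the highest lung-poor MYCN ON value of 4.49, and the immediate early score was also above its highest, 3.82.

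The scores of 3 further lists did not pass the test. Apoptosis regulators had 2 of 25 higher and 2 lower in MYCN ON, as many adjusted over the list alone, and DESeq2 called 8. The BH3-only genes Bid (4.84-fold) and Hrk (log2 fold change 3.25) were higher, and Birc3 and Casp8 were 3.88-fold and 2.14-fold higher in MYCN OFF. The calls of Birc3 (log2 fold change -1.34, adjusted p = 0.0617) and Casp8 (-1.05, adjusted p = 0.0687) were lost without MYCN OFF tumor 1, and that of Casp8 also without tumor 4 (-0.99, adjusted p = 0.0795). Leaving out MYCN OFF tumor 2 gave 4 lower apoptosis genes. Of 24 ATF4-related stress genes, 4 were higher and 2 lower, and 3 were higher and 1 lower adjusted over the list alone. Psat1, of serine synthesis, was 4.37-fold higher in MYCN ON and Ddit3, which encodes CHOP, 2.27-fold higher in MYCN OFF. Leaving out MYCN OFF tumor 1 gave 2 higher members, the lower members numbered 1 without any tumor but MYCN ON tumor 1 or MYCN OFF tumor 2, and with library totals the median of this list turned from 0.24 to -0.10. Hypoxia genes had 5 of 20 higher and 1 lower, as many adjusted over the list alone, with Mxi1 at 3.25-fold, and Pfkfb4 was 2.93-fold higher in MYCN OFF. Leaving out MYCN OFF tumor 3 gave 3 higher hypoxia genes. Birc3, Casp8, Psat1 and Pfkfb4 lost their call with the lung score as a covariate, and limma voom did not call Hrk (adjusted p = 0.0587). In the lung score fit 2 apoptosis, 0 ATF4-related and 1 hypoxia genes were called higher, and with the immune score 1, 0 and 0 were. At an unadjusted p below 0.05 the lung score fit had 2 ATF4-related genes in either direction (DESeq2 1, limma voom 1). Adjusted exact permutation p-values of the scores were 0.6 for apoptosis, 0.6 for the ATF4 list and 0.307 for hypoxia. By camera with an estimated correlation the adjusted p-values were 0.913, 0.869 and 0.539.

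Antigen presentation and interferon response genes were lower together in MYCN ON. Of 29 interferon response genes, 25 were lower and 0 higher (27 lower adjusted over the list alone). Irf1, a transcription factor of interferon signaling, was at 19.5 ± 6.94 against 76.0 ± 16.1 CPM (log2 fold change -1.96, SE 0.27, edgeR adjusted p = 8.47e-04). Stat2 and Oasl1 were 3.40-fold and 10.6-fold higher in MYCN OFF. Of 15 MHC class I presentation genes, 12 were lower, and 12 also adjusted over the list alone. Tap2, the peptide transporter subunit, was at 7.01 ± 5.01 against 60.6 ± 25.8 CPM (log2 fold change -3.11, SE 0.51, edgeR adjusted p = 0.00172), and Psmb8, Tapbp and H2-T23 were 8.04-fold, 5.36-fold and 7.57-fold higher in MYCN OFF. B2m, chosen after its value was seen, was 5.61-fold higher in MYCN OFF, and its log2 fold change moved from -2.49 to -1.43 without MYCN OFF tumor 1 and was -0.81 with the lung score as a covariate (adjusted p = 0.31). H2-K1, chosen in the same way, was 3.58-fold higher in MYCN OFF, a call lost without any tumor but MYCN ON tumor 5 or MYCN OFF tumor 2. H2-T23 has close paralogs and is uncertain to that extent. The scores differed by -2.79 for interferon and -2.01 for MHC class I, each with every MYCN ON tumor below every MYCN OFF tumor (adjusted exact permutation p = 0.00909). By camera with an estimated correlation the adjusted p was 0.215 and 0.243. Lung markers moved with both lists, and with the lung score as a covariate 11 interferon and 7 MHC class I genes were called lower. With the immune score in its place, 3 and 4 were, and Stat2 (adjusted p = 0.0502) missed the threshold. In the lung-poor MYCN OFF tumor 2 the scores were 3.88 and 5.75, above the highest lung-poor MYCN ON values of 2.33 and 4.48.

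**Figure D3:**
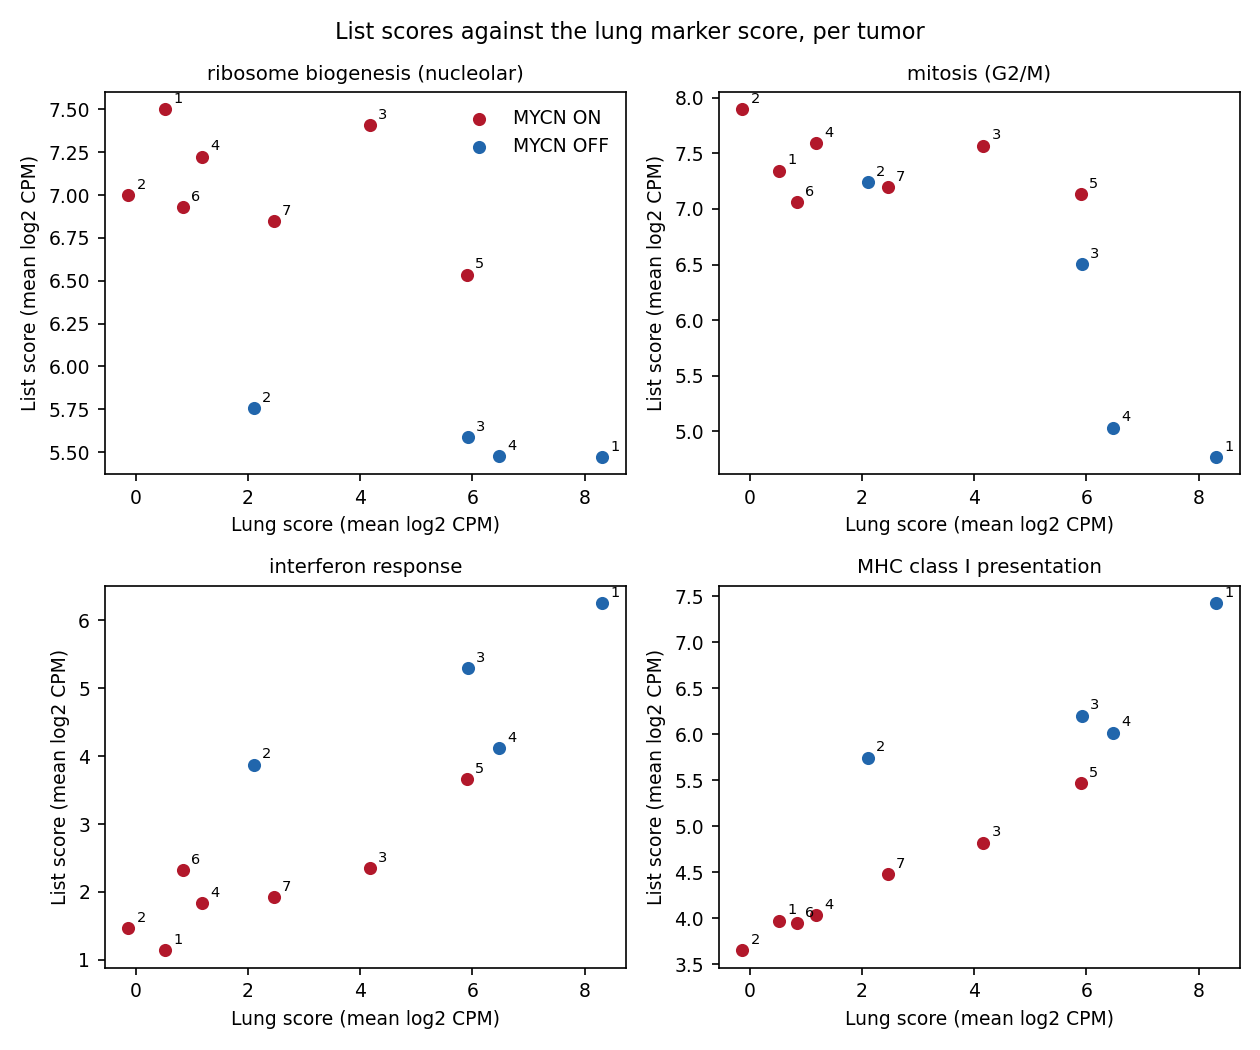
Score per tumor (mean log2 CPM) of 4 gene lists against the lung score (mean log2 CPM of alveolar and airway markers), for 7 MYCN ON (red) and 4 MYCN OFF (blue) tumors numbered by replicate. At a low lung score, MYCN OFF tumor 2 lies at 7.24 for mitosis, among the MYCN ON tumors, and at 5.75 for MHC class I, above them.

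Many marker genes of immune cells and of endothelium were called lower in MYCN ON. The list of MHC class II and dendritic cell genes had 11 of 14 members lower, T and NK cells 6 of 9, B and plasma cells 8 of 9, macrophages 10 of 20 and endothelium 8 of 16. Adjusted over the list alone, these counts were 11, 7, 9, 12 and 12. DESeq2 called 11, 7, 9, 12 and 12 genes and limma voom 9, 5, 8, 7 and 1, so the endothelium count depended on the tool. Ciita, the regulator of MHC class II, and Cd74, the invariant chain, were 5.94-fold and 6.70-fold higher in MYCN OFF. Cd3d and Cd8a of T cells were 7.45-fold and 6.18-fold higher, Cd79b and Pou2af1 of B cells 6.91-fold and 4.66-fold, the macrophage genes C1qa and Apoe 2.69-fold and 3.93-fold, and Kdr and Tie1 of endothelium 3.40-fold and 3.81-fold. Cd3d and Cd8a had few reads, at 0.556 ± 0.321 against 4.23 ± 4.88 CPM and 0.826 ± 0.428 against 5.18 ± 5.51 CPM. In MYCN OFF tumor 2 they had 7 and 9 reads, and both lay within the MYCN ON range there. The adjusted exact permutation p of the score was 0.0154 for MHC class II, 0.02 for T and NK cells and 0.02 for B and plasma cells, and the scores of macrophages (0.1) and endothelium (0.0952) did not pass. By camera with an estimated correlation the adjusted p-values were 0.342, 0.397, 0.344, 0.426 and 0.449. In the lung-poor MYCN OFF tumor 2 the scores of MHC class II, T and NK, and B and plasma cells were 3.16, 0.24 and 1.96, above the highest lung-poor MYCN ON values of 2.63, -0.13 and 1.07. Its macrophage and endothelium scores of 3.92 and 2.66 lay within the lung-poor MYCN ON ranges of 3.48 to 4.47 and 2.57 to 3.35. Many calls rested on MYCN OFF tumor 1, the one with most Sftpc. Leaving it out gave 2 MHC class II, 0 T and NK, 1 B and plasma, 5 macrophage and 0 endothelium genes. At an unadjusted p below 0.05 there were then 5 T and NK genes (DESeq2 0, limma voom 1) and 1 endothelium gene (DESeq2 1, limma voom 0). In that fit Cd8a, Cd3d, Cd79b, Kdr and Tie1 lost their call, with log2 fold changes of -1.60, -1.76, -1.89, -1.07 and -0.90. Leaving out MYCN OFF tumor 2 gave 12 T and NK genes, with more members past the low-count filter, and 13 endothelium genes. Without MYCN OFF tumor 4 or MYCN ON tumor 2, MHC class II gave 7, and without MYCN OFF tumor 3 or MYCN ON tumor 2, B and plasma cells gave 5. Endothelium gave 2 without MYCN ON tumor 1, 2, 4 or 7, 3 without MYCN ON tumor 3 or MYCN OFF tumor 4, and 4 without MYCN ON tumor 6. With the lung score as a covariate edgeR called 0 members of these 5 lists. At an unadjusted p below 0.05 there were then 2 MHC class II, 0 T and NK, 2 B and plasma, 4 macrophage and 0 endothelium genes, DESeq2 called 1 B and plasma and 2 macrophage genes, and limma voom 1 macrophage gene.

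The lung epithelial lists had 5 of 16 alveolar and 4 of 12 airway genes lower in MYCN ON, 5 and 6 adjusted over the list alone, and limma voom called 3 alveolar genes. Foxj1, a marker of ciliated cells, was at 3.01 ± 4.25 against 48.6 ± 62.0 CPM, Tppp3, another, was 7.40-fold higher in MYCN OFF, and the alveolar genes Abca3 and Emp2 2.60-fold and 5.61-fold. The scores did not pass the test (adjusted exact permutation p = 0.1 for alveolar and 0.0579 for airway genes; adjusted p = 0.431 and 0.344 by camera with an estimated correlation). Without MYCN OFF tumor 1, 1 alveolar and 2 airway genes were called, Foxj1 (log2 fold change -2.54), Tppp3 (-1.63) and Emp2 (-1.87) lost their call, and Abca3 moved from -1.38 to -0.85. Emp2 also lost it without MYCN ON tumor 4 (-2.41), MYCN ON tumor 6 (-2.39) or MYCN OFF tumor 4 (-2.41). The alveolar count was 1 to 3 when any of the MYCN ON tumors other than tumor 5, or MYCN OFF tumor 4, was left out, and the airway count was 11 without MYCN ON tumor 5. Neutrophil markers had 1 of 5 members lower and 0 adjusted over the list alone or by limma voom, with Csf3r at 2.92 ± 1.63 against 8.91 ± 6.23 CPM, a call that was lost without any tumor but MYCN ON tumor 5 and MYCN OFF tumor 2, where 2 and 4 members were lower. Without MYCN OFF tumor 3 the neutrophil list had 1 lower member. In the fibroblast list 0 of 20 and in the muscle list 0 of 13 members were called by edgeR. At an unadjusted p below 0.05 there were 3 and 1, DESeq2 called 2 and 1, and limma voom 0 and 1. Thy1 of the fibroblast list was at 14.7 ± 8.48 against 38.3 ± 29.9 CPM, and Ckm of muscle at 2.83 ± 5.07 against 28.1 ± 46.6. Thy1 passed with each of the other scalings, the stricter low-count filter, the replicate block and DESeq2 (adjusted p = 0.0196 to 0.0486), and Ckm with the replicate block, 1 surrogate variable and DESeq2 (adjusted p = 0.0126 to 0.0227). A fibroblast gene was called lower without MYCN ON tumor 4, MYCN ON tumor 6, MYCN OFF tumor 2 or MYCN OFF tumor 3, and 7 muscle genes were without MYCN ON tumor 5 and 2 without MYCN ON tumor 2. Adjusted exact permutation p-values of the scores were 0.138 for neutrophils, 0.6 for fibroblasts and 0.132 for muscle. By camera with an estimated correlation the adjusted p-values were 0.606, 0.808 and 0.449.

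Most neuroendocrine genes were not called between the groups. Of 30 neuroendocrine genes, 27 were not called, 1 was higher and 2 were lower in MYCN ON, with 1 and 1 adjusted over the list alone, and DESeq2 called 6. Uchl1 was at 682 ± 71.5 against 388 ± 98.1 CPM, and Scg2, a secretory granule protein, at 56.6 ± 28.4 against 392 ± 230 CPM (log2 fold change -2.79, SE 0.45, edgeR adjusted p = 0.00172). Chgb was at 110 ± 51.4 against 258 ± 121 CPM, and its call was lost when any tumor but MYCN ON tumor 6, MYCN ON tumor 7 or MYCN OFF tumor 1 was left out. The count of lower genes was 1 in most of these fits, 4 without MYCN OFF tumor 1 and 7 without MYCN ON tumor 7. The higher genes numbered 2 without MYCN ON tumor 7 or MYCN OFF tumor 2, and with the lung score as a covariate Uchl1 and Chgb lost their call. Uchl1 also missed it with library totals as the scaling (adjusted p = 0.0575). Calca and Chga, neuroendocrine genes chosen after their values were seen, were at 170 ± 316 against 1095 ± 1419 CPM and at 351 ± 316 against 707 ± 352 CPM and were not called (log2 fold changes -2.69 and -1.01, adjusted p = 0.123 and 0.209). Both passed without MYCN ON tumor 7 (-4.39 and -1.53, adjusted p = 0.015 and 0.0366) and by limma voom with sample quality weights (adjusted p = 0.028 and 0.0318), and without MYCN OFF tumor 4 Calca moved to -1.23. The quality weights gave MYCN OFF tumor 3 the most weight. Neurod1 ranged from 0 to 247 CPM in MYCN ON and from 1.36 to 53.7 in MYCN OFF, with an adjusted p of 0.619. Rb1 was at 141 ± 28.2 against 87.4 ± 22.7 CPM (adjusted p = 0.0342), a call that was lost without any tumor but MYCN ON tumors 2, 4 and 5 or MYCN OFF tumor 2, and with RLE factors (adjusted p = 0.0519), upper quartile factors (0.097) and library totals (0.178). The counts of Rb1 and Trp53 cover whole genes and do not check the deletion of single exons. In the neuronal list 0 of 17 genes were called by edgeR, with 2 at an unadjusted p below 0.05, 2 by DESeq2 and 2 by limma voom, and Elavl3 was at 525 ± 184 against 250 ± 141 CPM (adjusted p = 0.0521). It passed without MYCN ON tumor 1 (adjusted p = 0.044) and without MYCN OFF tumor 2 (adjusted p = 0.0129), as well as by DESeq2, both limma voom fits, the replicate block and 1 surrogate variable (adjusted p = 0.00529 to 0.0429), and another member was lower without MYCN ON tumor 6. The score tests gave adjusted exact permutation p-values of 0.113 and 0.988 for the neuroendocrine and neuronal lists, and camera with an estimated correlation gave adjusted p-values of 0.669 and 0.875. The neuroendocrine score differed by -0.55, by -0.78 with the lung score as a covariate (adjusted permutation p = 0.127) and by -1.11 with the immune score (adjusted permutation p = 0.0236), so that it passed in the last of these.

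In the Notch list 1 of 17 genes was higher and 2 were lower, as many adjusted over the list alone, and DESeq2 called 5. Rbpj, the transcription factor of the pathway, rose 2.11-fold, and Notch4, an endothelial receptor, was 3.81-fold higher in MYCN OFF. In the YAP-TAZ and non-neuroendocrine list 2 of 16 were lower and 0 adjusted over the list alone (9 at an unadjusted p below 0.05, DESeq2 9, limma voom 1), with Epha2 and Anxa1 at 4.12-fold and 3.46-fold higher levels in MYCN OFF. Both lost their call without MYCN OFF tumor 1 (log2 fold changes of -1.53 and -1.24) and without tumor 4 (-2.01 and -1.58), and Anxa1 also without MYCN OFF tumor 3 (-1.99) and without each of MYCN ON tumors 1, 2, 3, 6 and 7. Lower Notch genes numbered 1 without MYCN OFF tumor 1 or 4 and 4 without MYCN ON tumor 6. Lower YAP-TAZ genes numbered 9 without MYCN OFF tumor 2 and 0 without MYCN OFF tumor 1 or 4. Rbpj, Epha2 and Anxa1 lost their call with the lung score as a covariate. The YAP-TAZ genes numbered 4 without MYCN ON tumor 5, and 1 without MYCN OFF tumor 3 or MYCN ON tumor 1, 2, 3 or 7. The adjusted exact permutation p of the scores was 0.065 and 0.193, and by camera with an estimated correlation the adjusted p was 0.426 and 0.539.

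**Figure D4:**
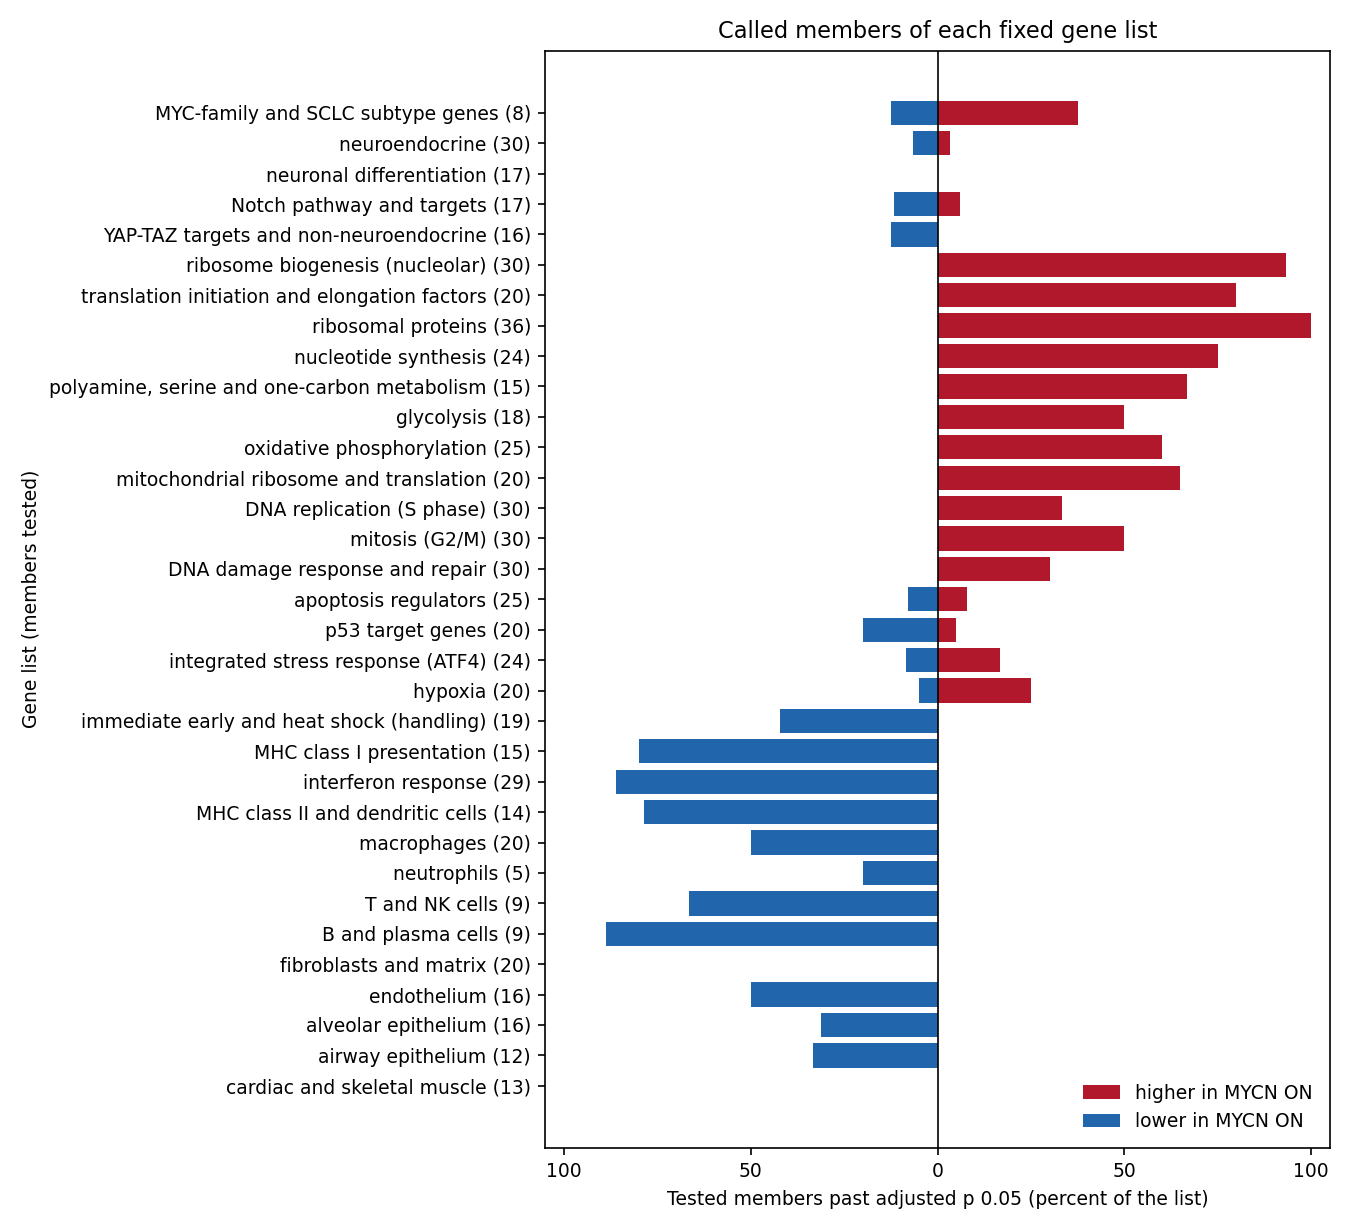
Share of the tested members of each of 33 gene lists (number tested in parentheses) past an edgeR adjusted p of 0.05, to the right if higher and to the left if lower in MYCN ON, from 7 and 4 tumors. All 36 ribosomal protein genes are to the right and 25 of 29 interferon response genes to the left.

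In all, camera with its preset correlation called 11 lists higher and 14 lower, and 0 of them with an estimated correlation (lowest adjusted p = 0.176, 6 lists at an unadjusted p below 0.05). Fry called 21 lists, and the exact permutation of list scores 18, of which 11 were higher and 7 lower in MYCN ON. Of these 18 scores, 8 no longer passed with the lung score as a covariate (glycolysis, mitosis, replication, repair, immediate early, MHC class II, T and NK, and B and plasma cells), with adjusted permutation p-values of 0.0813 to 0.287. The same 8 did not pass with the immune score, which itself contains the T and NK and the B and plasma cell lists. Other scalings kept the direction of the list medians given here, apart from the ATF4 list.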

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

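Except for the length and GC test, the tests in this part were chosen after the results were seen.

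The scores of MHC class I presentation and interferon response genes were lower in every MYCN ON tumor than in every MYCN OFF tumor, and many immune and some lung marker genes were called lower too. With the lung score as a covariate the MYCN ON minus MYCN OFF difference was -1.63 for interferon (58.4% of the unadjusted difference, permutation p = 0.00300) and -1.07 for MHC class I (53.3%, permutation p = 8.50e-04). Lung tissue stays open as a cause, because a marker score may measure it imperfectly and the markers were uneven between the groups. With the immune score as a covariate the differences were -1.20 (43.0%, permutation p = 0.0116) and -0.88 (43.7%, permutation p = 0.0155). More immune cells in the MYCN OFF tumors cannot be told apart from a change within tumor cells, since bulk counts do not separate the cells and immune cells may themselves carry these transcripts. A direct effect of MYCN or of doxycycline itself stays open and was not tested.

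The ribosome biogenesis score was higher in every MYCN ON tumor than in every MYCN OFF tumor, with 28 of 30 members called higher. A lower share of tumor cells in MYCN OFF would lower neuroendocrine genes alike, but the neuroendocrine score differed by -0.55 (exact permutation p = 0.0818), so it was not lower in MYCN OFF. The ribosome biogenesis score minus the neuroendocrine score differed by 2.04 (exact permutation p = 0.00303), which follows from the 2 scores and is no separate test. Neuroendocrine genes may themselves change between the groups, as Scg2 did (log2 fold change -2.79). By neuroendocrine genes the share of tumor cells therefore stays open. With the lung score as a covariate the ribosome biogenesis difference was 1.28 (85.9% of the unadjusted difference, permutation p = 2.80e-04). With the immune score it was 1.36 (91.1%, permutation p = 4.40e-04). These values argue against lung or immune tissue, as far as the scores measure it, as the main cause. Other tissue was not tested. After removal of the length and GC trend of each tumor the difference was 1.67 against 1.49 before (exact permutation p = 0.00303, 98.9% of genes matched to a transcript). The length and GC result argues against such a bias as the whole cause. A response to MYCN is a hypothesis from the same data. An effect of doxycycline itself cannot be told apart from it, and other technical causes were not excluded.

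The share of records aligned to several places, which entered no gene count, was 16.4% on average in MYCN ON against 11.05% in MYCN OFF (exact permutation p = 0.00303). Within the 7 MYCN ON tumors it followed the ribosomal protein score (Pearson r = 0.913, permutation p = 0.00794; Spearman rho = 0.893, permutation p = 0.0123). Without MYCN ON tumors 1 and 5, r was 0.899 over 5 tumors (exact permutation p = 0.025). Ribosomal protein reads shared with other genomic copies may therefore be part of this share, which was the only relation of this kind computed.

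Single tumors stood apart from the rest of their group in 23 of 298 sets of values tested (7.72%), where chance gives about 5%. Each set held the values of a gene, list score or library measure in MYCN ON or MYCN OFF. The rule was Dixon's gap ratio, the gap to the nearest tumor over the whole range. It can flag a tumor of similar level when the others lie close together. The sets are not independent, so the 5% is only a guide. In MYCN OFF tumor 1, Neurod1 was at 1.36 CPM (others 31.5 to 53.7), Npm1 at 440.1 CPM (340.2 to 343.5), Cox5a at 88.8 CPM (68.8 to 71.4), Foxj1 at 141 CPM (15.4 to 20.9) and Psma6 at 95.4 CPM (83.9 to 84.6). Its score of ATF4-related genes was 4.51 (4.27 to 4.31). MYCN OFF tumor 4 had Rb1 at 53.4 CPM (97.5 to 99.6), Scml4 at 60.5 CPM (39.0 to 41.4), Odc1 at 71.6 CPM (107 to 111), Aen at 10.5 CPM (24.1 to 26.0) and Junb at 104.97 CPM (39.6 to 45.3). In MYCN OFF tumor 3, Bzw2 was at 92.0 CPM (71.5 to 74.5) and Casp8 at 24.3 CPM (44.2 to 49.3).

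Among the MYCN ON tumors, tumor 2 had Notch4 at 3.45 CPM (others 7.32 to 11.6), Junb at 8.85 CPM (18.6 to 25.8), a DNA replication score of 7.05 (6.42 to 6.69) and an immediate early score of 2.60 (3.35 to 3.82). Nlrp1a was at 76.5 CPM in tumor 3 (48.8 to 58.7), Cox5a at 226 CPM in tumor 5 (132 to 163), Mrps5 at 59.2 CPM in tumor 6 (74.0 to 87.6) and Mrpl12 at 147 CPM in tumor 1 (94.4 to 110.5). Cdkn1a was at 72.9 CPM in tumor 7 (20.6 to 33.9) and Abca3 at 37.8 CPM in tumor 4 (63.2 to 88.4).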

How the results depend on the processing

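The tests with lung or immune scores as covariates and those within lung-poor or lung-containing tumors were chosen after the results were seen. RLE and upper quartile factors, both low-count filters, 1 surrogate variable, DESeq2 and both limma voom fits gave 3922 to 6039 genes against 4475. The 6039 genes came from limma voom with sample quality weights, which weighted MYCN OFF tumor 3 most. Leaving out each tumor in turn gave 2862 to 5393 genes, 1674 to 2955 higher and 1015 to 2438 lower, a Mycn log2 fold change of 2.80 to 3.21, 23 to 26 lists by camera (11 to 12 higher, 12 to 14 lower) and 13 to 25 lists by score. The spread between tumors rather than depth limited the calls, and 1 count equals 0.0676 to 0.116 CPM. For all of the changes below the cause was not tested, unless the setting itself uses fewer tumors or a stricter threshold.

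Library totals gave 1317 genes higher in MYCN ON and 3347 genes lower in MYCN ON, and the ATF4 list median turned to -0.10. With no low-count filter the MYC-family median was -0.17. An adjusted p below 0.01 gave 1703 genes (1187 higher, 516 lower), at which 21 of 111 named genes were no longer called, and a test for changes above 1.5-fold 1456 (796 and 660), where 18 were not. Neurod1 turned to -0.26 with limma voom and to -0.95 with sample quality weights, where the MYC-family median was -0.38 and that of apoptosis genes 0.0110. Fry gave 9 lists lower, and camera with an estimated correlation 0 lists in all, 0 higher and 0 lower (6 at an unadjusted p below 0.05; fry 21). With each tumor left out, the apoptosis median was -0.10 to 0.0136, turning to 0.0136 without MYCN ON tumor 6. Trp53 was at -0.40 to 0.0120 and the fibroblast median at -0.70 to 0.16, both turning without MYCN OFF tumor 1.

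Deviations of equal replicate numbers correlated by -0.162, 0.462, -0.0763 and 0.265, and 2 of 4 MYCN OFF tumors correlated best with their own number, which does not settle pairing. The Y-linked gene Ddx3y was at 110 CPM in MYCN ON tumor 2 and 0 in MYCN OFF tumor 2. It was at 0.0882 CPM in MYCN ON tumor 4 and 80.2 in MYCN OFF tumor 4. These values argue against a shared animal for numbers 2 and 4, and numbers 1 and 3 stay open. The replicate block gave 3024 genes, 2494 of them shared, with 1152 genes lower in MYCN ON, Neurod1 at -0.86, Trp53 at 0.00420 and neuronal genes at -0.47.

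With the lung score as a covariate there were 1311 genes, 927 genes higher in MYCN ON and 384 genes lower in MYCN ON, and 8 lists lower. Trp53 turned to 0.12, Anxa1 to 0.10, Sftpc to 1.47 and Scgb1a1 to 0.70, and list medians to 0.18 for YAP-TAZ, 0.18 for apoptosis, 0.47 for neutrophils, 0.35 for fibroblasts, 0.0863 for endothelium and 0.85 for alveolar genes, where Sftpc, Scgb1a1 and the alveolar list are part of the score. The immune score gave 996 genes (663 and 333) and 15 lists, 4 of them lower. Trp53 turned to 0.26, Cd3d to 0.0903, Tie1 to 0.22, Sftpc to 1.56 and H2-K1 to 0.39. List medians turned to 0.48 for YAP-TAZ, 0.0621 for apoptosis, 0.0855 for macrophages (part of the score, as is Cd3d), 0.26 for neutrophils, 1.15 for fibroblasts (camera adjusted p = 0.00219), 0.43 for endothelium, 0.56 for alveolar genes and 0.10 for muscle.

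Within lung-poor tumors edgeR gave 0 genes, 0 higher and 0 lower (2288 at an unadjusted p below 0.05, DESeq2 830, limma voom 3), Mycn at 2.79 (adjusted p = 0.194) and 9 lists lower. The lone MYCN OFF tumor is assumed there to vary like the others. Trp53 turned to 0.15, Anxa1 to 1.15 and Scgb1a1 to 0.54, and list medians to 0.31 for Notch, 0.81 for YAP-TAZ, 0.28 for apoptosis, 0.31 for macrophages, 0.54 for fibroblasts and 0.38 for endothelium. Lung-containing tumors gave 0 genes, 0 higher and 0 lower (3898 at an unadjusted p below 0.05, DESeq2 2503, limma voom 0) and the targeted gene Mycn at 2.89 (adjusted p = 0.0987).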

Other observations

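The tests of the additional gene lists in this part were chosen after the results were seen, so their p-values are not independent evidence. These lists had no covariate fit, no fit with a tumor left out and no camera test. The splits of the tumors were planned.

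Most tested genes of cholesterol synthesis, of the cytosolic chaperonin and prefoldin, and of the proteasome were higher in MYCN ON. In cholesterol synthesis 12 of 20 genes were higher and 0 lower, with Fdft1, squalene synthase, at a log2 fold change of 1.34 (SE 0.16, edgeR adjusted p = 5.00e-04). The cytosolic chaperonin and prefoldin list had 13 of 14 higher, with Cct6a at 1.71 (SE 0.17, adjusted p = 3.28e-04), and the proteasome 16 of 23, with Psma6 at 1.02 (SE 0.12, adjusted p = 5.00e-04). Each of these 3 scores was higher in every MYCN ON tumor (adjusted exact permutation p = 0.00505 over 5 lists). In the lung-poor MYCN OFF tumor 2 they were 5.25, 7.06 and 6.89, below the lowest lung-poor MYCN ON values of 5.49, 7.77 and 7.38.

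Of 25 lysosome genes 8 were lower in MYCN ON, among them Pld3 at -1.47 (SE 0.22, adjusted p = 0.00124), and the score differed by -0.58 (adjusted exact permutation p = 0.0303). The score of the lung-poor MYCN OFF tumor 2 was 6.13, within the 6.01 to 6.44 of the lung-poor MYCN ON tumors. In the circadian clock list 1 of 18 genes was higher and 4 lower, with Nr1d1 and Dbp at -1.88 and -1.99 (adjusted p = 5.62e-04 and 0.00600), and the score differed by -0.48 (adjusted exact permutation p = 0.0455). The clock score of MYCN OFF tumor 2 was 5.19, also within the 4.42 to 5.22 of the lung-poor MYCN ON tumors. The labels used here give no time of day of collection.

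Xist was at 2.21 CPM in MYCN ON tumor 2, 6.48 in MYCN ON tumor 5 and 46.2 in MYCN OFF tumor 4, and at 1301 to 4082 in the other tumors. Ddx3y, a Y-linked gene, was at 110, 109 and 80.2 CPM in those 3 tumors. MYCN OFF tumor 4 held 493 Xist reads against 25 and 83 in the other 2, and these counts leave open whether it holds RNA of more than 1 animal. It was kept in the comparison, and without it 2922 genes were called in place of 4475. Xist, Ddx3y, Acta1, Myh6 and Actc1 lie outside the rule for named genes. The skeletal muscle genes Ckm and Acta1 were at 97.9 and 152 CPM in MYCN OFF tumor 2 and at 13.8 and 43.2 CPM in MYCN ON tumor 2. The cardiac genes Myh6 and Actc1 were at 114 and 100.3 CPM in MYCN ON tumor 5, 140.3 and 93.4 in MYCN OFF tumor 1, and 171 and 60.2 in MYCN OFF tumor 3, against 35.5 and 25.1 in MYCN OFF tumor 2.

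Of the 330 possible splits of the 11 tumors into 7 and 4, 100 were run, and 1 gave as many called genes, the real split with 4475 genes. The highest other split gave 1 called gene, so an arbitrary split is unlikely to give the gene count. Every other split put MYCN ON and MYCN OFF tumors together in a group, which can raise the spread within groups and lower their counts. The distance between 4475 genes and 1 gene therefore does not measure the strength of the evidence. The splits do not separate MYCN from lung content, which was uneven between the real groups. For gene lists called by camera, 11 of 100 splits gave at least as many as the real 25, the highest other being 29, so chance is not excluded for the number of lists.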
